A study of Mus musculus and Rattus norvegicus with 51 samples.

How the data were processed

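RNA was sequenced from HSC-T6 cells, a rat cell line derived from hepatic stellate cells, and from whole mouse liver, per the labels' protocols. Liver RNA was isolated with an RNAspin kit and cell RNA with a miRNeasy kit, and libraries were made with the TruSeq Stranded mRNA chemistry, per the labels. The deposited values are whole-number read counts per gene, which the authors gave in 3 tables of 12, 18 and 21 libraries. The unit was settled from the values, since the column totals differed between libraries. The submitters' processing notes name the mouse build mm10 for all libraries, the rat ones included. The aligner, the counting tool, the annotation and the strand setting are not given in the sources used here. Genes that overlap on opposite strands and near-identical family members (the Mup, Cyp2a, Cyp2b, Cyp4a, Sult2a and Gsta families, for example) are therefore uncertain. All 51 columns of counts were matched to samples by their names, and 0 columns were left without a sample.

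The cell table held 17327 genes, and its libraries held 11752661 to 16981255 counts on genes. The table of fibrosis and resolution livers held 24421 genes and 8355714 to 16327132 counts per library. The table of MO and CCl4 livers held 24982 genes and 22598631 to 39323123 counts per library. Rows for reads without a gene or with more than 1 gene were left out of totals and tests. Reads without a gene came to 24.2% to 26.0% of the gene counts in the cell table and 5.18% to 7.78% in the MO and CCl4 table. Ambiguous reads came to 0.211% to 0.244% and 0.538% to 1.53%. The 10 most abundant genes took 9.04% to 12.2% of the counts in the cells, 6.65% to 8.71% in the fibrosis and resolution livers and 17.6% to 23.1% in the MO and CCl4 livers. Of the symbols of the MO and CCl4 livers, 26 had the form of dates, as a spreadsheet writes them, and were kept as they stood. A RefSeq gene table of GRCm38.p6 held 95.0% and 97.7% of the symbols of the liver tables, and positions were taken from it.

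Each table was tested on its own with edgeR 4.0.16 in R 4.3.3. Genes were kept by filterByExpr with a minimum count of 10 and a minimum total of 15, which left 10140 genes in the cells, 13487 in the fibrosis and resolution livers and 14129 in the MO and CCl4 livers. Counts were scaled by TMM factors. 1 robust quasi-likelihood model with all groups of a table was fitted, and a gene was called at a Benjamini-Hochberg adjusted p under 0.05. All adjusted p-values of genes come from this edgeR test unless another tool is named. Levels are CPM, counts scaled to a common library total with TMM factors, given as mean ± SD. Fold changes are log2 values with their standard error (SE). Where all libraries of a group held 0 counts, a lower bound of the fold was taken against a floor of 3 counts summed over the group. Floors and counting intervals cover counting error only.

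There were 21 comparisons. For the cells, each HMGB1 form was compared with BSA and with each other form. For the livers, each treatment was compared with BSA within its stage, the treatments within a stage with each other, and the BSA livers of both stages with each other. In the last table CCl4 was compared with MO within each genotype, both HMGB1 constructs with each other under each injection, their CCl4 responses with each other, and the knockout with wild-type HMGB1 with the wild-type liver. The labels do not say whether numbered samples are separate cultures or animals, so p-values measure the spread between these samples, which may be technical. No pair of libraries within a group held identical counts, and every such pair differed beyond sampling noise (lowest chi-square per degree of freedom 1.50 in the cells and 11.6 in each liver table).

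Fixed lists, 36 in all, were tested with camera of limma 3.58.1 at a preset inter-gene correlation of 0.01. Their p-values were adjusted over the lists of a comparison. Log2 CPM had a prior count of 2. Lists needed 5 measured members. Camera with an estimated correlation and fry, which tests whether a list's genes move on balance one way, were run beside it. Counts of list members past the test are given over all genes tested and, where they differ, adjusted over the list alone. The matrix lists were fibrillar collagens and fibrosis matrix, activated stellate cell and myofibroblast, quiescent stellate cell, TGF-beta response, and matrix proteases and inhibitors. The inflammation lists were cytokines and chemokines, NF-kB feedback and targets, immediate early, interferon-stimulated, acute phase, and HMGB1 and its receptors. The cell type lists were infiltrating and scar-associated macrophage, Kupffer cell, neutrophil, T and NK cell, B and plasma cell, sinusoidal endothelium, cholangiocyte, mesothelium, and pericentral and periportal hepatocyte. The metabolism and stress lists were bile acids, cholesterol synthesis, lipogenesis, fatty acid oxidation, antioxidant and NRF2, xenobiotic receptor targets, cell cycle, unfolded protein and integrated stress response, p53 response, circadian clock, and male-biased and female-biased liver genes. Erythroid, acinar pancreas and mitochondrially encoded lists had at most 2 members past the filter in any table and could not be tested.

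Named genes are Hmgb1, up to 4 members of each described list with the largest changes past the test (or else its most abundant member), and the genes with the largest rises and falls whose replicates did not overlap and whose higher group had a mean of at least 1 CPM. Of these, 10 were taken each way in the main comparisons and 5 in the others. The groups, tests, lists, this rule and most of the alternatives were fixed before the data were examined. A few genes outside the rule are named as such, and 1 gene is not reported here.

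The replicate numbers of the titles were checked for pairing by correlating deviations from the group means. Every pair exceeded 0.1 in 6 comparisons, which count as paired: [H] against BSA (0.187 to 0.521), [O] against BSA (0.474 to 0.595) and [O] against [H] (0.274 to 0.708) in fibrotic liver, the 2 constructs under CCl4 (0.108 to 0.261) and under MO (0.289 to 0.454), and the knockout with wild-type HMGB1 against wild-type liver under CCl4 (0.116 to 0.313). The pairing comes from the numbers and these correlations; the labels name no shared animal or day.

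The alternatives were DESeq2 1.42.0 (also its size factors alone), no filter, the replicate block, a fit of only the groups compared, and leaving out each library. Sex-linked transcripts were found in libraries labelled male, so a covariate for the share of female RNA and a fit without Xist-holding libraries were added after seeing the data. Also added then were a block within only the groups compared, and a fit without the fibrosis libraries numbered 2. For comparisons with common controls, 100 draws of unchanged groups gave the covariance of fold changes that the controls alone produce. The procedure was tested on simulated data, with 200 changed genes in each of 3 simulations. At 1.5, 2 and 4 fold it recovered 92.4%, 95.5% and 100% of the changed genes of [O] against BSA in the cells (10063 genes). It recovered 1.49%, 22.4% and 83.3% for [O] against BSA in fibrotic liver (13355 genes), and 27.3%, 77.3% and 93.9% for the constructs under CCl4 (13971 genes).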

Results

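The series asks how redox forms of HMGB1 bear on the progression and the resolution of liver fibrosis, per its title. HMGB1 is a nuclear DNA-binding protein that stressed and dying cells release, and it is known in forms that differ in the oxidation of its cysteines. The labels write the forms as [H], [O] and [SO3] and do not spell these out. RNA was sequenced from 51 libraries. HSC-T6 cells, a rat line derived from hepatic stellate cells (the cells that lay down scar matrix in injured liver), were given BSA or 1 of the 3 forms for 6 h, with 3 libraries each. The cell libraries held 11.8 to 14.6 M gene counts with BSA, 15.6 to 16.03 M with [H], 16.1 to 16.9 M with [O] and 15.8 to 17.0 M with [SO3] HMGB1.

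Whole livers of wild-type mice formed 6 further groups of 3. The fibrosis groups received CCl4, a hepatotoxin whose repeated injection scars the liver, for 4 weeks, together with BSA (10.99 to 14.0 M gene counts), [H] HMGB1 (12.0 to 16.3 M) or [O] HMGB1 (13.6 to 14.6 M). The resolution groups had regressed for 1 week and received BSA (8.36 to 14.9 M), [SO3] HMGB1 (10.001 to 11.01 M) or an HMGB1 antibody (9.64 to 12.0 M). A last set, deposited under a name with AAV8, compared MO with CCl4 after 4 weeks (MO and AAV8 are not spelled out). Its groups were wild-type livers (3 with MO at 22.6 to 31.4 M, 4 with CCl4 at 27.2 to 34.0 M) and livers of the genotype Hmgb1ΔHepΔMye, a deletion of Hmgb1. The Hmgb1ΔHepΔMye livers had received wild-type HMGB1 (3 with MO at 26.5 to 39.3 M, 4 with CCl4 at 28.6 to 33.8 M) or a form labelled Δ[O] HMGB1 (3 with MO at 26.5 to 32.8 M, 4 with CCl4 at 26.9 to 35.4 M).

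The first question was what each form does to stellate cells in culture. With [H] HMGB1 fewer genes changed than with the other forms, and single inflammatory genes were lower than with BSA. Ccl2, a chemokine that attracts monocytes, fell (30.8 ± 3.33 against 49.7 ± 2.55 CPM, SD, n = 3 each; log2 -0.69, SE 0.09, adjusted p = 0.00167). Il1rn, which encodes the interleukin-1 receptor antagonist, also fell (12.5 ± 0.956 against 20.6 ± 0.922 CPM, log2 -0.73), as did Serpinb2, a serine protease inhibitor gene (2.46 ± 0.309 against 5.11 ± 0.377 CPM, log2 -1.06), and Ptgs2, the inducible prostaglandin synthase (log2 -0.44). Apln, a peptide hormone gene, rose (10.7 ± 0.516 against 7.09 ± 0.0118 CPM, log2 0.59), and so did the microfibril gene Fbn1 (log2 0.24) and the proliferation marker Mki67 (log2 0.19). Of the TGF-beta response list, 5 of 15 members fell, among them Tgfb3 (log2 -0.24) and Id2 (log2 -0.53). The list itself gave no call, with a median log2 fold change of 0.03, a mean of -0.05 and a camera adjusted p of 0.0515. Of the cytokine list 1 of 13 fell (2 adjusted over the list alone), and of the collagen and fibrosis matrix list 1 of 17 rose (1 and 3 adjusted over the list alone).

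In all, 81 of 10140 genes changed with [H] HMGB1 by edgeR, 32 higher and 49 lower, but 454 did in a fit of only these groups, 168 with no filter, 139 with DESeq2 and 39 with the replicate block. The interferon-stimulated list had a median log2 fold change of -0.72 with 0 of 15 members past the test (camera adjusted p = 1.36e-05, adjusted p = 0.588 with an estimated correlation). Much of that shift rests on BSA library 3 (mean centred log2 scores -0.511 to 0.785 with BSA, -0.888 to -0.616 with [H]). Camera also placed lipogenesis (0 of 14 rose, 3 adjusted over the list alone, camera adjusted p = 0.0385, adjusted p = 0.588 with an estimated correlation) and cell cycle (1 of 26 rose, camera adjusted p = 0.043, adjusted p = 0.589 with an estimated correlation) higher. None of these 3 camera calls held with an estimated correlation. The count moved widely when 1 library was left out, to 195, 14 and 46 without BSA libraries 1, 2 and 3, and to 46, 13 and 18 without [H] libraries 1, 2 and 3. Of 27 named genes past the test, 9 kept their call in each of these fits, among them Ccl2, Il1rn and Ptgs2. Apln lost it without BSA 2 or [H] 2 (adjusted p up to 0.114), Tgfb3 without BSA 2, [H] 2 or [H] 3 (up to 0.158), and Fbn1 without these or BSA 3 (up to 0.105). Mki67 lost it without any library but BSA 3 (up to 0.235) and Id2 without any but BSA 1 (up to 0.203).

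With [O] HMGB1, HSC-T6 cells took on an inflammatory transcript profile. Every measured member of the cytokine and chemokine list rose (13 of 13, median log2 fold change 4.26; camera adjusted p = 2.1e-94, adjusted p = 5.64e-06 with an estimated correlation). Cxcl1, which attracts neutrophils, reached 693 ± 28.9 against 6.72 ± 1.29 CPM (SD, n = 3 each; log2 6.71, SE 0.08, adjusted p = 9.27e-27). Ccl20, a ligand of CCR6, reached 26.4 ± 0.84 against 0.0454 ± 0.0786 CPM (log2 8.84, SE 0.28, adjusted p = 7.9e-19), Cxcl6 126 ± 2.97 against 0.317 ± 0.0532 CPM (log2 8.58) and the membrane chemokine Cx3cl1 295 ± 7.7 against 1.41 ± 0.434 CPM (log2 7.68). Among targets and feedback regulators of NF-kB, 14 of 15 rose (camera adjusted p = 1.53e-147, adjusted p = 5.64e-06 with an estimated correlation). They included the adhesion molecules Vcam1 (601 ± 45.5 against 6.88 ± 0.863 CPM, log2 6.46) and Icam1 (1618 ± 17.2 against 136 ± 4.28 CPM, log2 3.57) and the regulators Bcl3 (log2 5.19) and Nfkbiz (log2 4.56).

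The largest rises with [O] HMGB1 also took in Nos2, the inducible nitric oxide synthase (log2 8.48), the guanylate-binding protein gene Gbp5 (log2 7.52) and Tlr2, a pattern recognition receptor (log2 7.34). Cd69 and Niacr1 held 0 counts in all BSA libraries and 91 and 59 counts over the [O] libraries. Of the acute phase list 3 of 5 rose (camera adjusted p = 0.000162, adjusted p = 0.0246 with an estimated correlation), with Lcn2, an iron-sequestering protein gene, at log2 8.23. The largest falls included Hey1, a Notch target (-2.81), and Lbh, a transcription cofactor gene (108 ± 16.7 against 605 ± 40.6 CPM, log2 -2.48). The p53 list rose in 7 of 10 members (camera adjusted p = 2.88e-05, adjusted p = 0.00968 with an estimated correlation), led by Plk2 (log2 2.21) and Btg2 (log2 1.68). The bile acid list rose in 4 of 6 (camera adjusted p = 0.0011, adjusted p = 0.0246 with an estimated correlation), chiefly through Cyp7b1, an oxysterol hydroxylase gene (68.8 ± 1.41 against 2.57 ± 0.368 CPM, log2 4.75).

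Matrix and myofibroblast transcripts moved both ways with [O] HMGB1. Acta2, which encodes smooth muscle actin and marks activated stellate cells, rose (1140.1 ± 28.3 against 647 ± 7.53 CPM; log2 0.82, SE 0.03, adjusted p = 6.55e-17), and so did Pdgfra (415 ± 10.4 against 104 ± 1.14 CPM, log2 1.99), a growth factor receptor. Pdgfrb fell (log2 -0.44), as did Spon2 (log2 -0.71). Over the myofibroblast list 6 rose and 6 fell of 17 (camera adjusted p = 0.34). Over the collagen and fibrosis matrix list 5 rose and 4 fell of 17 (camera adjusted p = 0.602). Postn stood at log2 0.25, Col3a1 at -0.21 and Col14a1 at -0.34. The TGF-beta response list had 5 higher and 6 lower of 15 (camera adjusted p = 0.18), with Tgfb3 lower at log2 -1.29.

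Cell cycle transcripts fell in 20 of 26 members, by small amounts (median log2 fold change -0.21; camera adjusted p = 0.00307, adjusted p = 0.336 with an estimated correlation), with Ccne2 at log2 -0.51 and E2f1 at -0.45. Cholesterol synthesis genes fell in 11 and rose in 3 of 20 (camera adjusted p = 0.18). Lipogenesis genes fell in 9 and rose in 1 of 14 (camera adjusted p = 0.11). Interferon-stimulated genes rose in 5 of 15 (camera adjusted p = 0.00206, adjusted p = 0.468 with an estimated correlation). Immediate early genes rose in 8 and fell in 4 of 17 (camera adjusted p = 0.00307, adjusted p = 0.0761 with an estimated correlation). Altogether 4453 genes changed, 2408 higher and 2045 lower, and 347 and 150 of them by at least 2 fold. Of 9 camera calls, 5 held with an estimated correlation.

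With [SO3] HMGB1 the response was of another kind, with stress transcripts higher and matrix transcripts lower than with BSA. Antioxidant and NRF2 genes rose in 9 of 10 (camera adjusted p = 1.19e-35, adjusted p = 2.48e-05 with an estimated correlation). Hmox1, the inducible heme oxygenase, reached 1226 ± 39.6 against 80.1 ± 2.35 CPM (SD, n = 3 each; log2 3.94, SE 0.04, adjusted p = 7.99e-28), Srxn1, a sulfiredoxin gene, 470.4 ± 7.24 against 75.9 ± 4.45 CPM (log2 2.63), and Slc7a11, a cystine importer gene, rose by log2 2.24. The p53 list rose in 9 of 10 (camera adjusted p = 9.21e-43, adjusted p = 1.04e-05 with an estimated correlation), with the stress cytokine Gdf15 at 26.4 ± 0.779 against 0.0758 ± 0.0715 CPM (log2 8.33) and the cell cycle inhibitor Cdkn1a at 1032 ± 35.5 against 189 ± 6.43 CPM (log2 2.45). Immediate early genes rose in 16 of 17 (camera adjusted p = 6.18e-33, adjusted p = 2.48e-05 with an estimated correlation), among them Atf3 (log2 3.73), Fosl1 (log2 3.39) and Egr1 (log2 2.82).

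Fibrillar collagens and fibrosis matrix genes fell in 14 of 17 with [SO3] HMGB1, and 0 rose (median log2 fold change -0.46; camera adjusted p = 2.43e-07, adjusted p = 0.00763 with an estimated correlation). Col14a1 fell most (log2 -0.96), followed by Thbs2, a matricellular protein gene (1619 ± 26.2 against 2433 ± 17.1 CPM, log2 -0.59), Col1a2 (log2 -0.58) and Fbn1 (log2 -0.58). The myofibroblast list fell in 9 and rose in 2 of 17 (camera adjusted p = 0.139). Matrix proteases and inhibitors fell in 9 and rose in 2 of 15 (camera adjusted p = 0.0411, adjusted p = 0.164 with an estimated correlation). Cell cycle genes fell in 22 and rose in 1 of 26 (camera adjusted p = 3.91e-15, adjusted p = 0.0086 with an estimated correlation), with the mitotic kinase Plk1 at 31.4 ± 2.22 against 89.1 ± 2.58 CPM (log2 -1.51) and Cenpf, a kinetochore protein gene, at log2 -1.21.

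Inflammatory transcripts also rose with [SO3] HMGB1, in 12 of 13 cytokines and chemokines (camera adjusted p = 3e-22, adjusted p = 8.14e-05 with an estimated correlation) and 11 of 15 NF-kB genes (camera adjusted p = 3.41e-19, adjusted p = 0.00123 with an estimated correlation). Cxcl1 reached 205 ± 14.2 against 6.72 ± 1.29 CPM (log2 4.95) and the cytokine Il6 72.4 ± 4.2 against 2.7 ± 0.265 CPM (log2 4.73). Cholesterol synthesis genes fell in 12 and rose in 2 of 20 (camera adjusted p = 0.0405, adjusted p = 0.31 with an estimated correlation), with Hmgcs1, an early enzyme of that pathway, at 230.2 ± 9.23 against 462 ± 21.9 CPM (log2 -1.01). In total 6420 genes changed, 3155 higher and 3265 lower, and 324 and 241 of them by at least 2 fold. Of 9 camera calls, 7 held with an estimated correlation.

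**Figure D1:**
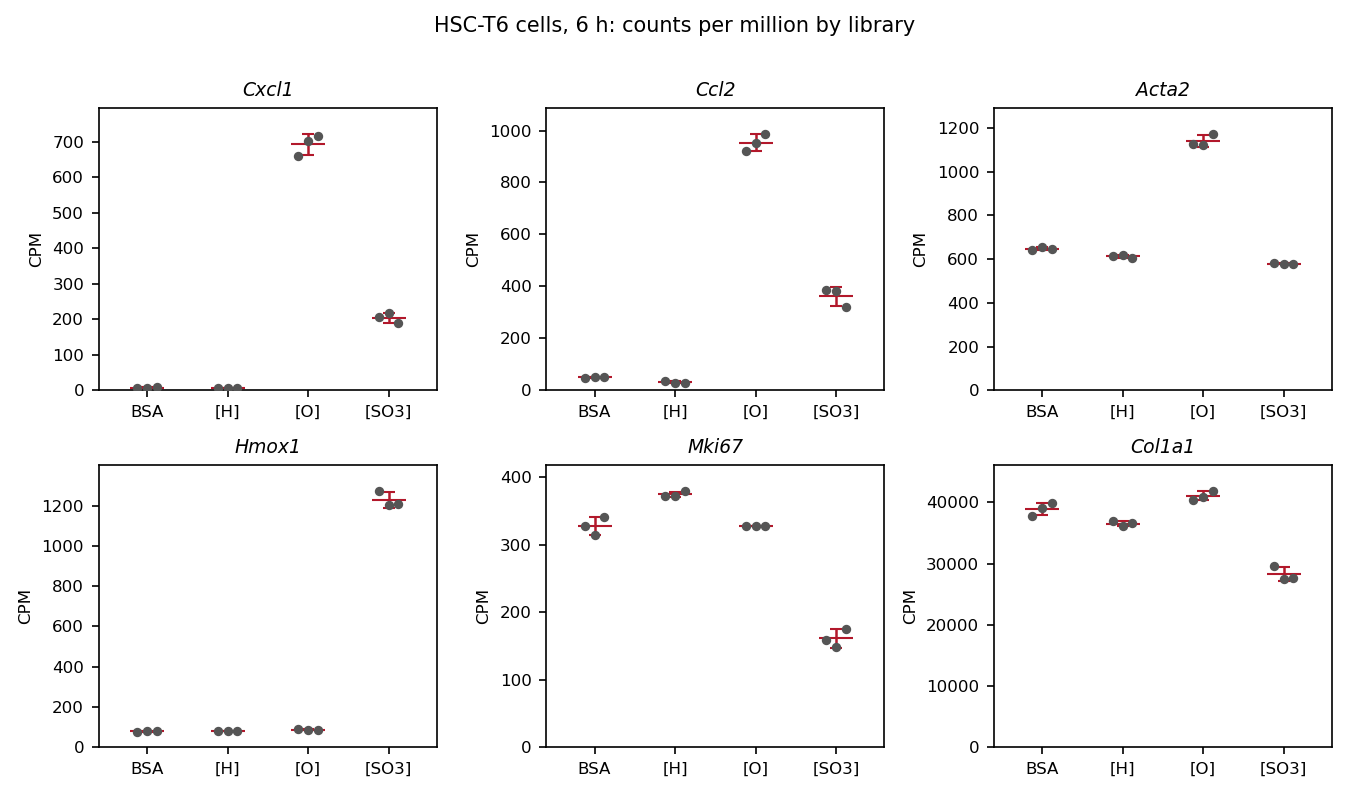
Levels of 6 genes in HSC-T6 cells given BSA, [H], [O] or [SO3] HMGB1 for 6 h, as CPM per library (points) with mean and SD (red), 3 libraries per group. Cxcl1 averaged 693 CPM with [O] against 205 with [SO3] HMGB1, and Hmox1 1226 CPM with [SO3] against 88.7 with [O] HMGB1.

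The forms were then compared directly. Set against [O] HMGB1, [SO3] HMGB1 gave lower cytokine and NF-kB transcripts and higher antioxidant and immediate early transcripts. Vcam1 stood at 5.03 ± 0.624 against 601 ± 45.5 CPM (SD, n = 3 each; log2 -6.90), Cxcl6 at log2 -7.77 and Ccl20 at log2 -6.45. Csf3, which encodes granulocyte colony-stimulating factor, held 0 counts in every [SO3] library and 2.83 ± 0.366 CPM (135 counts) with [O] HMGB1. Over the lists, 10 of 13 cytokines (camera adjusted p = 1.55e-25, adjusted p = 2.51e-05 with an estimated correlation) and 13 of 15 NF-kB genes were lower (14 adjusted over the list alone). Hmox1 was higher with [SO3] HMGB1 (1226 ± 39.6 against 88.7 ± 4.26 CPM, log2 3.79), with 9 of 10 antioxidant and NRF2 genes and 16 of 17 immediate early genes.

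The activation markers parted as well. Acta2 was lower with [SO3] than with [O] HMGB1 (579.9 ± 2.79 against 1140.1 ± 28.3 CPM; log2 -0.98, SE 0.03, adjusted p = 1.46e-18), as were Pdgfra (log2 -2.66) and Fn1, the fibronectin gene (log2 -0.63). Collagen and fibrosis matrix genes were lower in 15 of 17 (camera adjusted p = 2.28e-05, adjusted p = 0.0184 with an estimated correlation), and the myofibroblast list was lower in 8 and higher in 3 of 17 (camera adjusted p = 0.0121, adjusted p = 0.042 with an estimated correlation). Interferon-stimulated genes were lower in 7 of 15 (camera adjusted p = 0.000352, adjusted p = 0.405 with an estimated correlation), and cell cycle genes in 17 of 26 (camera adjusted p = 9.27e-06, adjusted p = 0.0948 with an estimated correlation). Between these forms 6000 genes differed, 2953 higher and 3047 lower with [SO3], and 10 of 12 camera calls held with an estimated correlation.

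Against [H] HMGB1, [O] HMGB1 changed 4139 genes (2216 higher, 1923 lower) and [SO3] HMGB1 6431 genes (3199 higher, 3232 lower). All 13 cytokines were higher with [O] (median log2 fold change 6.26; camera adjusted p = 7.56e-100, adjusted p = 3.17e-07 with an estimated correlation), and so were 12 of 15 interferon-stimulated genes (camera adjusted p = 3.65e-05, adjusted p = 0.384 with an estimated correlation). With [SO3], collagen and fibrosis matrix genes were lower in 13 of 17 (camera adjusted p = 1.95e-06, adjusted p = 0.00992 with an estimated correlation) and all 17 immediate early genes were higher (camera adjusted p = 1.49e-32, adjusted p = 6.31e-05 with an estimated correlation). Of the camera calls, 5 of 10 and 7 of 8 held with an estimated correlation. Hmgb1 itself measured 37.2 ± 1.04 CPM with [H], 36.9 ± 2.23 with [O], 36.6 ± 0.692 with [SO3] and 40.8 ± 4.52 with BSA (adjusted p = 0.333, 0.0986 and 0.0539). Without BSA library 1 it passed the test for [O] (adjusted p = 0.0109) and [SO3] (0.00445), and over all alternatives it ran up to 0.487 and 0.341.

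The [O] and [SO3] responses shared 1400 higher and 1287 lower genes, where independent lists would share 749 and 658, and 389 and 205 genes went opposite ways, where 775 and 636 would. Both were set against the same BSA libraries, so part of the excess may come from those controls. The covariance of their log2 fold changes was 0.144, and unchanged groups simulated against the same controls gave 0.0131. The values for [H] with [O] (0.0125, simulated 0.0132) and [H] with [SO3] (0.0160, simulated 0.0131) lay near the simulated ones. With no filter on low counts they lay above them (0.24 and 0.241, simulated 0.152 and 0.155).

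**Figure D2:**
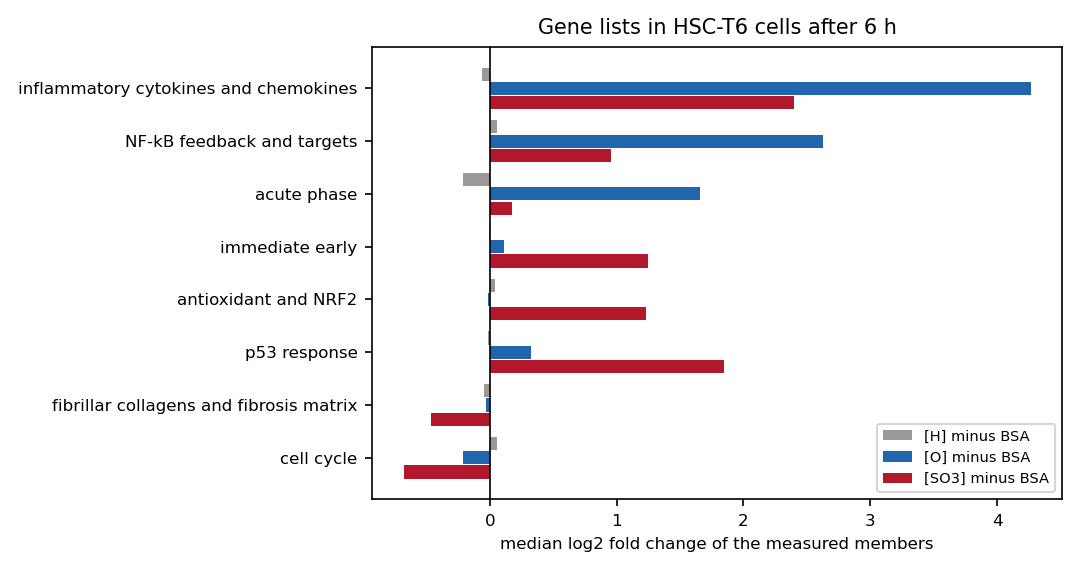
Median log2 fold change against BSA of 8 gene lists in HSC-T6 cells, as bars for [H], [O] and [SO3] HMGB1. The cytokine list stood at 4.26 with [O] HMGB1, and the collagen and fibrosis matrix list at -0.03 with [O] and -0.46 with [SO3] HMGB1.

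In mouse liver, the fibrosis groups asked whether added [H] or [O] HMGB1 changes the liver under CCl4. No single gene passed the test for either form against BSA, while matrix and immune cell lists lay lower with [H] and matrix lists higher with [O]. Collagen and fibrosis matrix genes had a median log2 fold change of -0.85 with [H] (12 of 20 lower adjusted over the list alone, 0 over all genes; camera adjusted p = 3.39e-10, adjusted p = 0.324 with an estimated correlation). The cell cycle list stood at -2.18 (camera adjusted p = 5.92e-07, adjusted p = 0.426 with an estimated correlation). Much of both differences rests on BSA library 3, the highest in each. Mean centred log2 scores ran from -0.0489 to 1.22 with BSA and -0.679 to 0.0497 with [H] for the collagen list, and from -1.09 to 3.3 and -0.707 to 1.25 for the cell cycle list. Neutrophil genes stood at -1.84 (camera adjusted p = 4.02e-07, adjusted p = 0.324 with an estimated correlation) and sinusoidal endothelium genes at -0.74 (camera adjusted p = 2.12e-11, adjusted p = 0.324 with an estimated correlation). S100a9, a neutrophil calcium-binding protein gene, measured 11.6 ± 3.74 CPM with [H] and 42 ± 23.6 CPM with BSA (n = 3 each, adjusted p = 0.418). With [O], the collagen list stood at 0.49 (camera adjusted p = 2.02e-07, adjusted p = 0.497 with an estimated correlation) and the myofibroblast list at 0.59 (camera adjusted p = 6.23e-06, adjusted p = 0.497 with an estimated correlation). Fatty acid oxidation stood at -0.33 (2 of 17 lower adjusted over the list alone; camera adjusted p = 2.02e-07, adjusted p = 0.497 with an estimated correlation).

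Between the forms, collagen and fibrosis matrix genes lay higher with [O] than with [H], at a median log2 fold change of 1.32 (16 of 20 higher adjusted over the list alone, 0 over all genes; camera adjusted p = 2.68e-27, adjusted p = 0.0767 with an estimated correlation). The myofibroblast list followed at 1.01 (14 of 20 adjusted over the list alone; camera adjusted p = 4.95e-16, adjusted p = 0.12 with an estimated correlation), with its most abundant member Vim, an intermediate filament gene, at 156 ± 64.6 CPM with [O] and 62 ± 27.1 CPM with [H] (adjusted p = 0.131). Col1a1, a chain of type I collagen named after its values were seen, averaged 286 ± 11.4 CPM with [O], 45.5 ± 15.4 with [H] and 165 ± 216 with BSA, whose libraries held 50.4, 30.3 and 414 CPM (adjusted p = 0.135 for [O] against [H]). Neutrophil genes stood at 2.05 (8 of 11 adjusted over the list alone; camera adjusted p = 2.56e-09, adjusted p = 0.196 with an estimated correlation) and infiltrating macrophage genes at 0.94 (8 of 17; camera adjusted p = 1.8e-10, adjusted p = 0.195 with an estimated correlation). Camera called 21, 16 and 22 lists in the 3 comparisons, and 0 held with an estimated correlation. Libraries 2 and 3 of each of the 3 groups held Xist, the RNA that silences 1 X chromosome in female cells, at 66 to 946 CPM although all are labelled male.

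By edgeR 0 genes passed in these comparisons. For [H], [O] and [O] against [H], 1448, 727 and 1413 had an unadjusted p under 0.05, and DESeq2 called 2, 6 and 274. The replicate block, which spanned unpaired resolution livers too, gave 1 for [O] against [H]. A paired fit of only those groups, chosen after seeing the data, gave 230. Without [O] library 1, 1 gene passed for [O] and 16 for [O] against [H], and 1 for the latter without [H] library 2. The B and plasma cell call of [H] (adjusted p = 0.0563) and the cell cycle call of [O] (0.0596) were lost with the block, and the NF-kB list of [O] gained one (0.0374). The covariance of the [H] and [O] fold changes was 0.142 beside 0.0993 in simulation, which did not keep the pairing of libraries by number, so part of the excess may come from it. Hmgb1 measured 161 ± 14 CPM with [H], 142 ± 11.9 with [O] and 151 ± 6.34 with BSA.

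In resolving liver, the question was whether [SO3] HMGB1 or an HMGB1 antibody alters the week of regression. Again no gene passed edgeR's test. Female-biased liver genes lay higher with [SO3] HMGB1 in every list member adjusted over the list alone (15 of 15, 0 over all genes; median log2 fold change 7.28; camera adjusted p = 1.89e-46, adjusted p = 0.00525 with an estimated correlation). Cyp2a4, a female-biased steroid hydroxylase gene, measured 384 ± 194 CPM with [SO3] and 1.65 ± 0.809 CPM with BSA (n = 3 each, adjusted p = 0.171). [SO3] libraries 1 and 2 held Xist at 919 and 215 CPM and library 3 at 0.714, while the BSA and antibody libraries held at most 1.5 CPM. The collagen list gave no call (median log2 fold change -0.13, camera adjusted p = 0.548). Hspa5, the main chaperone of the endoplasmic reticulum, measured 578 ± 122 CPM against 1549 ± 518 (adjusted p = 0.401) within an unfolded protein list at a median of -0.42 (camera adjusted p = 0.000502, adjusted p = 0.7 with an estimated correlation).

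With the antibody, mesothelium genes, markers of the lining of the liver surface, lay higher (7 of 7 adjusted over the list alone, 0 over all genes; median log2 fold change 2.50; camera adjusted p = 6.29e-28, adjusted p = 0.0182 with an estimated correlation). Upk3b, one of them, measured 12.2 ± 6.44 CPM with the antibody, 11.5 ± 5.93 with [SO3] and 1.81 ± 0.522 with BSA. The acute phase list stood at 0.62 (camera adjusted p = 3.47e-17, adjusted p = 0.14 with an estimated correlation). The myofibroblast list stood at 0.44 (camera adjusted p = 4.1e-06, adjusted p = 0.438 with an estimated correlation) and the collagen list at 0.36 (camera adjusted p = 4.37e-05, adjusted p = 0.456 with an estimated correlation). Of the camera calls, 1 of 10 held with an estimated correlation for [SO3], 1 of 20 for the antibody and 1 of 12 between them, the last again the female-biased list (median 5.86; camera adjusted p = 1.74e-44, adjusted p = 0.00586 with an estimated correlation).

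For [SO3], the antibody and [SO3] against the antibody, 812, 279 and 516 genes had an unadjusted p under 0.05, and DESeq2 called 80, 3 and 35. A fit of only the groups compared called 49 genes for [SO3] and 9 against the antibody, and without the Xist-holding libraries 79 and 51 genes passed, a fit added after seeing the data that left 1 [SO3] library. Leaving out [SO3] library 3 gave 2 genes in each. The covariance of the [SO3] and antibody fold changes was 0.132, and 0.113 in simulation. Hmgb1 measured 191 ± 2.17 CPM with [SO3], 164 ± 26.9 with the antibody and 165 ± 16.9 with BSA.

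Resolution itself was read from the BSA livers of both stages. Scar, myofibroblast, infiltrating macrophage and proliferation transcripts were on average lower after 1 week of regression than at 4 weeks of CCl4, though single fibrosis libraries reached resolution levels. Acta2 fell from 29.3 ± 10.2 to 4.05 ± 1.58 CPM (SD, n = 3 each; log2 -2.85, SE 0.54, adjusted p = 0.0138), and Col1a1 from 165 ± 216 to 26.4 ± 12.2 CPM (log2 -2.64, adjusted p = 0.0372), with 50.4, 30.3 and 414 CPM in the fibrosis libraries and 39.8, 23.3 and 16.1 at resolution. Mmp12, the macrophage elastase, fell from 115 ± 73.1 to 7.93 ± 2.49 CPM (log2 -3.85), and the monocyte receptor Cd14 by log2 -3.82. In their place, Glul, the glutamine synthetase of hepatocytes around the central vein, rose from 135 ± 53.7 to 952 ± 75.6 CPM (log2 2.82).

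Of the myofibroblast list 10 of 20 fell (15 adjusted over the list alone; camera adjusted p = 1.22e-09, adjusted p = 0.211 with an estimated correlation). Of the collagen list 8 of 20 fell (15 adjusted over the list alone; camera adjusted p = 5.01e-06, adjusted p = 0.309 with an estimated correlation). Of the TGF-beta list 7 of 16 fell (13 adjusted over the list alone; camera adjusted p = 2.09e-07, adjusted p = 0.211 with an estimated correlation). Cell cycle genes fell in 19 of 26 (26 adjusted over the list alone; camera adjusted p = 1.22e-09, adjusted p = 0.309 with an estimated correlation), with Plk1 at log2 -4.77. Their score in fibrosis library 2, at -1.09, lay within the resolution range of -1.12 to -0.983, and Mki67 there measured 3.72 CPM beside 3.35 to 5.4 at resolution. Immediate early genes fell in 12 of 18 (camera adjusted p = 1.33e-09, adjusted p = 0.309 with an estimated correlation). Fibrosis library 2 stood apart in them, with the highest of scores from 0.101 to 3.52 and Fos at 141 against 5.98 and 7.47 CPM, while resolution scores ran from -1.5 to -1.27. Infiltrating macrophage genes fell in 9 of 17 (12 adjusted over the list alone; camera adjusted p = 2.59e-06, adjusted p = 0.265 with an estimated correlation). The Kupffer cell list of resident macrophages stood at -0.05 (camera adjusted p = 0.856). All 7 mesothelium genes fell (camera adjusted p = 1.47e-08, adjusted p = 0.211 with an estimated correlation). Male-biased genes rose in 3 of 17 (camera adjusted p = 1.22e-09, adjusted p = 0.299 with an estimated correlation). Female-biased genes fell in 10 of 15 (camera adjusted p = 4.1e-09, adjusted p = 0.211 with an estimated correlation). Xist itself averaged 527 ± 457 CPM at fibrosis, from 5.05, 721 and 856 in libraries 1 to 3, and 0.34 ± 0.254 CPM at resolution.

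In all 1214 genes differed, 324 higher and 890 lower at resolution, but 21 camera calls kept 0 with an estimated correlation. The count fell to 2, 0 and 1 when resolution BSA libraries 1, 2 and 3 were left out, to 634 without fibrosis BSA library 2, and rose to 2377 without fibrosis BSA library 1. Of 87 named genes past the test 0 kept their call through all 6 of these fits. Acta2 and Mmp12 lost it without any 1 of the resolution libraries (adjusted p up to 0.0897 and 0.0804), Col1a1 also without fibrosis library 3 (0.284), Cd14 also without fibrosis library 2 (0.266), and Plk1 also without fibrosis library 3 (0.302). Glul lost it in every one (up to 0.121). DESeq2 called 2329, a fit of only these groups 91, and fits added after seeing the data called 704 without the Xist-holding libraries, which left 1 fibrosis library, and 63 with the share of female RNA as a covariate.

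**Figure D3:**
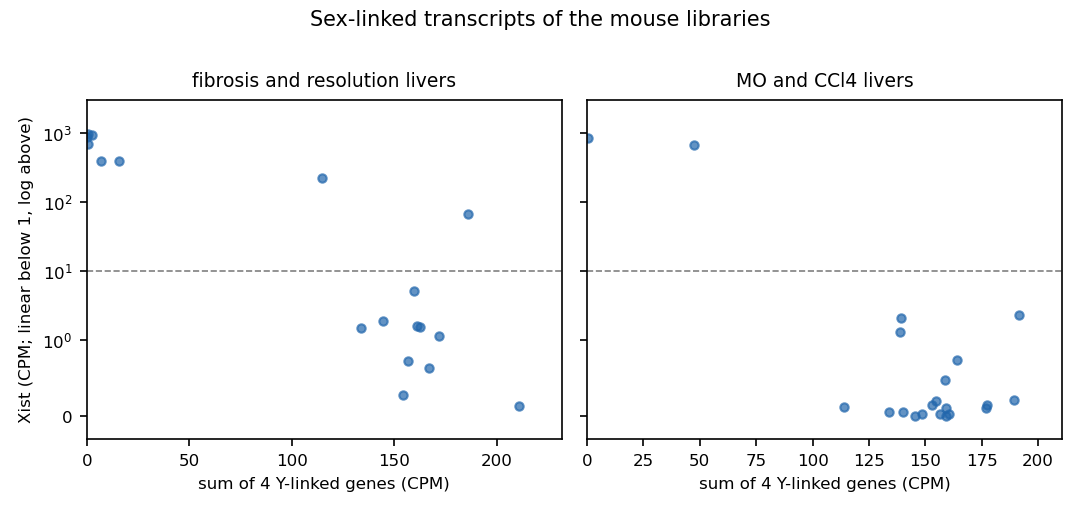
Sum of 4 Y-linked genes in CPM (x axis) against Xist in CPM (y axis, logarithmic above 1 and linear below), 1 point per liver library, with a dashed line at 10 CPM of Xist. The CPM drawn are scaled by library totals alone, without TMM factors. On the left are fibrosis and resolution livers and on the right MO and CCl4 livers, and all are labelled male.

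The last design deleted Hmgb1 and supplied HMGB1 again, so the Hmgb1 transcript came first. Hmgb1 (GRCm38.p6, chromosome 5, 149046702 to 149053057, protein coding) measured 72.8, 74.5 and 77.3 CPM in wild-type MO livers 1 to 3, and 65.5, 57.2, 69.5 and 107 CPM in wild-type CCl4 livers 1 to 4. With wild-type HMGB1 supplied, Hmgb1ΔHepΔMye livers held 69.7, 63.9 and 74.7 CPM under MO, and 50.5, 44.9, 65.4 and 74.1 CPM under CCl4 (livers 1, 3, 4 and 5). With Δ[O] HMGB1 they held 215, 172 and 131 CPM under MO, and 63.0, 81.2, 61.7 and 92.3 CPM under CCl4 (livers 1, 2, 3 and 5). The gene count does not separate the deleted gene from the supplied one, so the labels could not be checked by a loss of Hmgb1. Under MO, Hmgb1 with Δ[O] was 173 ± 42.2 CPM against 69.4 ± 5.42 with wild-type HMGB1 (log2 1.31, SE 0.23, adjusted p = 0.165). It passed with the replicate block (log2 1.30, adjusted p = 0.00535), and over all alternatives the adjusted p ran from 0.00023 to 0.937. It passed without wild-type HMGB1 MO library 3 (adjusted p = 0.00888) and without Δ[O] MO library 3 (0.034), the libraries that held Xist.

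Lyz2 (chromosome 10, 117277541 to 117282272), the myeloid lysozyme gene and the locus of a widely used myeloid Cre line, did separate the genotypes. It measured 6.83 ± 2.09 CPM in Hmgb1ΔHepΔMye livers with wild-type HMGB1 under CCl4 and 157 ± 50.3 CPM in wild-type CCl4 livers (n = 4 each; log2 -4.52, SE 0.34, adjusted p = 2.53e-07). Every Hmgb1ΔHepΔMye library lay between 1.76 and 9.51 CPM and every wild-type one between 94.7 and 218 CPM.

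CCl4 against MO in wild-type liver gave the injury response of this set. Scar matrix, myofibroblast, macrophage, stress and proliferation transcripts rose, and hepatocyte transcripts of the central vein zone fell. Col1a1 (chromosome 11, 94936224 to 94953042) reached 144 ± 49.8 against 7.85 ± 5.46 CPM (SD, n = 4 and 3; log2 4.20, SE 0.57, adjusted p = 1.61e-05), and Acta2 (chromosome 19, 34240336 to 34255585) 25.8 ± 12.3 against 1.83 ± 0.421 CPM (log2 3.83). Cyp2e1, the cytochrome that activates CCl4, fell to 465 ± 487 against 11562 ± 1351 CPM (log2 -4.64, or -5.65 without CCl4 liver 4, which held 1193 CPM against 170 to 262 in the others) and Glul to 55.4 ± 19.2 against 1515 ± 220.5 CPM (log2 -4.77). Gpnmb and Trem2, genes of lipid- and scar-associated macrophages, rose to 50.5 ± 12.8 against 0.766 ± 0.555 CPM and 8.68 ± 1.15 against 0.778 ± 0.307 CPM. Sprr1a, a cornified envelope protein gene, was at 0 counts in all MO libraries and at 16371 counts over the CCl4 libraries.

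Among matrix lists under CCl4 in wild-type liver, 18 of 20 collagen and matrix genes rose (camera adjusted p = 4.3e-13, adjusted p = 0.154 with an estimated correlation), as did 19 of 20 myofibroblast genes (camera adjusted p = 7.75e-10, adjusted p = 0.164 with an estimated correlation). So did 9 of 16 TGF-beta genes (10 adjusted over the list alone; camera adjusted p = 0.000286, adjusted p = 0.204 with an estimated correlation) and 14 of 20 proteases and inhibitors (camera adjusted p = 1.04e-06, adjusted p = 0.154 with an estimated correlation). Mmp12 rose by log2 5.72 and the crosslinking enzyme Lox by log2 4.30. Quiescent stellate cell genes rose in 6 and fell in 4 of 15 (camera adjusted p = 0.407). Cytokines rose in 11 of 16 (camera adjusted p = 0.0021, adjusted p = 0.333 with an estimated correlation), with Ccl2 at log2 3.26, and immediate early genes in 9 of 18 (12 adjusted over the list alone; camera adjusted p = 1.04e-06, adjusted p = 0.154 with an estimated correlation). NF-kB genes rose in 7 and fell in 2 of 16 (camera adjusted p = 0.126). Interferon-stimulated genes fell in 7 and rose in 1 of 20 (camera adjusted p = 0.181). Acute phase genes fell in 4 of 18 (2 adjusted over the list alone; camera adjusted p = 0.181). HMGB1 and its receptors rose in 6 and fell in 2 of 14 (camera adjusted p = 0.126).

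Cell type markers moved apart in the wild-type CCl4 livers. Infiltrating macrophage genes rose in 11 of 17 (camera adjusted p = 1.4e-05, adjusted p = 0.214 with an estimated correlation). Kupffer cell genes fell in 7 and rose in 1 of 13 (8 lower adjusted over the list alone; camera adjusted p = 0.000487, adjusted p = 0.335 with an estimated correlation). The Kupffer lectin Clec4f stood at 61 ± 10.5 against 214 ± 20.1 CPM (log2 -1.81). Neutrophil genes rose in 9 of 11 (camera adjusted p = 0.00634, adjusted p = 0.333 with an estimated correlation). No camera call was made for T and NK cells (1 rose and 3 fell of 15; adjusted p = 0.286), B and plasma cells (5 of 8 rose; 0.119), sinusoidal endothelium (2 rose and 3 fell of 16; 0.789), cholangiocytes (4 rose and 1 fell of 10; 0.0758) or mesothelium (0 of 7; 0.682).

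Most hepatocyte lists fell, and cholesterol synthesis rose. Pericentral genes fell in 12 of 16 (13 adjusted over the list alone; camera adjusted p = 9.87e-16, adjusted p = 0.0583 with an estimated correlation). Periportal genes fell in 9 and rose in 1 of 15 (camera adjusted p = 0.0201, adjusted p = 0.41 with an estimated correlation). Bile acid genes fell in 12 of 16 (camera adjusted p = 1.52e-05, adjusted p = 0.168 with an estimated correlation). The sterol hydroxylase Cyp8b1 fell to 11.7 ± 15.5 against 588 ± 142 CPM (log2 -5.67). Fatty acid oxidation genes fell in 13 of 17 (camera adjusted p = 2.11e-06, adjusted p = 0.168 with an estimated correlation). Cholesterol synthesis genes rose in 13 of 20 (camera adjusted p = 0.000286, adjusted p = 0.41 with an estimated correlation). Lipogenesis genes rose in 5 and fell in 3 of 15 (camera adjusted p = 0.705). Male-biased genes fell in 15 of 17 (17 adjusted over the list alone; camera adjusted p = 1.22e-06, adjusted p = 0.333 with an estimated correlation), the elongase Elovl3 by log2 -9.41. Of female-biased genes 3 of 15 rose (camera adjusted p = 0.607). Xenobiotic receptor targets fell in 6 and rose in 2 of 12 (camera adjusted p = 0.106). Clock genes fell in 2 and rose in 1 of 16 (0.286).

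Stress and growth lists rose with CCl4 in wild-type liver. Cell cycle genes rose in 19 of 26 (camera adjusted p = 2.7e-07, adjusted p = 0.333 with an estimated correlation). Unfolded protein and integrated stress response genes rose in 9 of 15 (camera adjusted p = 1.05e-06, adjusted p = 0.0998 with an estimated correlation), antioxidant and NRF2 genes in 9 of 15 (camera adjusted p = 0.000487, adjusted p = 0.114 with an estimated correlation). The p53 list rose in 9 of 12 (camera adjusted p = 0.000286, adjusted p = 0.164 with an estimated correlation). Slc7a11 rose to 14.6 ± 3.65 against 0.138 ± 0.164 CPM, the stress transcription factor gene Ddit3 to 34.9 ± 9.63 against 4.77 ± 0.723 CPM and the replication licensing gene Mcm2 to 30.2 ± 12.6 against 2.31 ± 0.338 CPM. In total 6542 of 14129 genes changed, 3219 higher and 3323 lower, and 1773 and 1000 by at least 2 fold. None of 19 camera calls held with an estimated correlation, while fry called 26 lists.

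In Hmgb1ΔHepΔMye livers CCl4 also raised matrix and cell cycle transcripts and lowered pericentral ones. With wild-type HMGB1, Col1a1 rose to 506 ± 126 against 9.71 ± 3.22 CPM (SD, n = 4 and 3; log2 5.70) and the proliferation marker Mki67 to 153 ± 45.3 against 7.95 ± 0.917 CPM (log2 4.26). With Δ[O] HMGB1, they rose to 230.5 ± 94.7 against 8.99 ± 6.1 CPM (log2 4.67) and 91.9 ± 43.3 against 5.9 ± 2.91 CPM (log2 3.95). Collagen genes rose in 19 and 17 of 20 (adjusted p = 0.141 with an estimated correlation for wild-type HMGB1, 0.0754 for Δ[O]), and all 26 cell cycle genes rose in both (adjusted p = 0.22 with an estimated correlation, and 0.0795 for Δ[O]). Pericentral genes fell in 14 and 14 of 16, the 1 call in each that held with an estimated correlation (adjusted p = 0.0356 and 0.0084). Unlike in wild-type liver, Kupffer cell genes rose with wild-type HMGB1 in 8 and fell in 2 of 13 (camera adjusted p = 0.0199, adjusted p = 0.776 with an estimated correlation), and unfolded protein genes rose in 2 and fell in 5 of 15 (camera adjusted p = 0.714); the difference between these responses was not tested. Interferon-stimulated genes fell in 15 of 20 with wild-type HMGB1 (camera adjusted p = 1.05e-07, adjusted p = 0.225 with an estimated correlation). Hmgb1 fell with Δ[O] (74.5 ± 14.8 against 173 ± 42.2 CPM, log2 -1.21), and measured 58.7 ± 13.4 against 69.4 ± 5.42 CPM with wild-type HMGB1 (adjusted p = 0.356). MO library 3 of each construct held Xist (845 CPM with wild-type HMGB1, 664 with Δ[O]). There were 6685 changed genes with wild-type HMGB1 (3298 higher, 3387 lower) and 3425 with Δ[O] (1818 higher, 1607 lower), or 2127 without Δ[O] MO library 2. Of the genes of the naming rule past the test, 101 of 127 with wild-type HMGB1 and 76 of 107 with Δ[O] kept their call under every alternative, Col1a1 and Mki67 among them in both.

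The wild-type livers and those with wild-type HMGB1, which had no libraries in common, shared 1936 higher and 1914 lower genes with CCl4, where independent lists would share 751 and 797. Tested directly, the CCl4 response with Δ[O] differed from that with wild-type HMGB1 in 0 genes by edgeR, with 2098 at an unadjusted p under 0.05 and 81 by DESeq2. The interaction rested on MO libraries as well: without wild-type HMGB1 MO library 3, which held Xist at 845 CPM, 1119 genes passed, and without Δ[O] CCl4 library 2, 25 did. Fits added after seeing the data called 768 genes without both Xist-holding libraries and 34 with the share of female RNA as a covariate, and the replicate block gave 3.

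**Figure D4:**
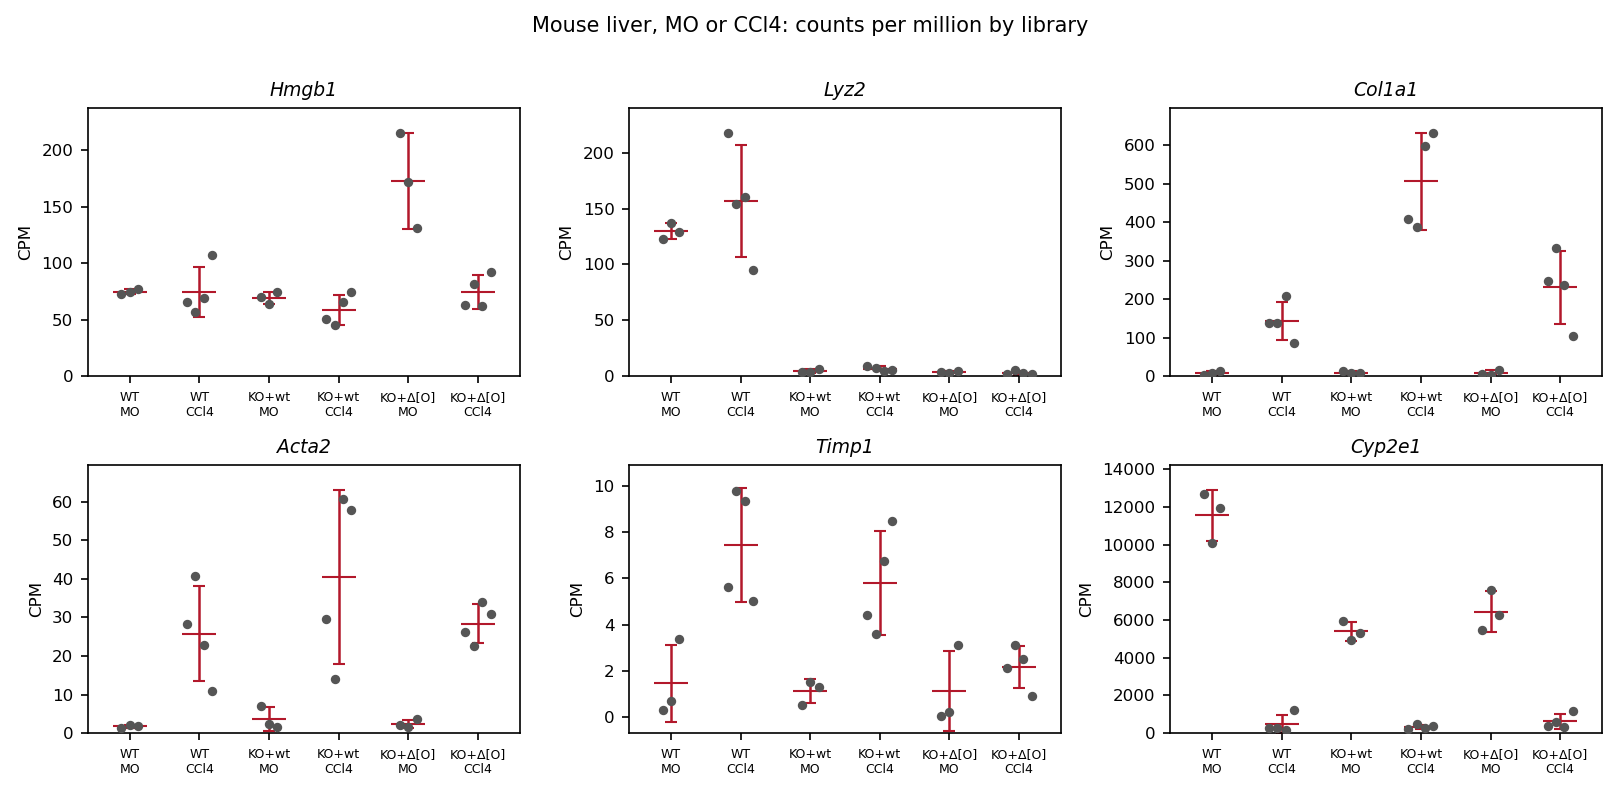
Levels of 6 genes in MO and CCl4 livers of wild-type mice (WT), Hmgb1ΔHepΔMye mice with wild-type HMGB1 (KO+wt) and with Δ[O] HMGB1 (KO+Δ[O]), as CPM per library (points) with mean and SD (red), 3 libraries per MO group and 4 per CCl4 group. Col1a1 under CCl4 averaged 144, 506 and 230.5 CPM in that order, and Lyz2 stayed under 10 CPM in all Hmgb1ΔHepΔMye livers.

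The comparison at the centre of this design set Δ[O] against wild-type HMGB1 under CCl4. Macrophage, inflammatory and matrix transcripts were lower with Δ[O], and lymphocyte markers lay lower too. Marco, a scavenger receptor of resident macrophages, measured 64.4 ± 38.1 against 331 ± 63.9 CPM (SD, n = 4 each; log2 -2.36, SE 0.42, adjusted p = 0.00762). Cd5l, a macrophage-secreted protein gene, measured 207 ± 76.1 against 428 ± 59.9 CPM (log2 -1.05) and Col6a3, a type VI collagen chain, 60.5 ± 18.6 against 127 ± 24 CPM (log2 -1.07, SE 0.22, adjusted p = 0.0124). Hmox1 was lower too (38.2 ± 7.85 against 76.7 ± 4.69 CPM, log2 -1.01), as was the profibrotic cytokine Tgfb1 (18.4 ± 3.35 against 30.0 ± 5.39 CPM, log2 -0.70).

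Kupffer cell genes fell in 7 of 13 (9 adjusted over the list alone; camera adjusted p = 4.75e-13, adjusted p = 0.14 with an estimated correlation), among them the haemoglobin scavenger receptor Cd163 (log2 -1.02) and Timd4 (log2 -1.09). Infiltrating macrophage genes fell in 2 of 17 (9 adjusted over the list alone; camera adjusted p = 1.7e-07, adjusted p = 0.177 with an estimated correlation). Collagen and fibrosis matrix genes fell in 5 of 20 (13 adjusted over the list alone; camera adjusted p = 4.75e-13, adjusted p = 0.177 with an estimated correlation), including Postn (log2 -1.01) and Fbn1 (log2 -0.94). The myofibroblast list fell in 1 of 20 (10 adjusted over the list alone; camera adjusted p = 1.28e-06, adjusted p = 0.292 with an estimated correlation). Cytokines fell in 2 of 16 (11 adjusted over the list alone; camera adjusted p = 1.58e-10, adjusted p = 0.14 with an estimated correlation), the chemokine Cxcl16 by log2 -1.03. NF-kB genes fell in 3 of 16 (9 adjusted over the list alone; camera adjusted p = 4.55e-07, adjusted p = 0.14 with an estimated correlation), Icam1 by log2 -0.84. T and NK cell genes (median log2 fold change -0.44, 1 of 15 lower; camera adjusted p = 0.00872, adjusted p = 0.177 with an estimated correlation) and B and plasma cell genes (-0.49, 1 of 8 lower; camera adjusted p = 0.0336, adjusted p = 0.374 with an estimated correlation) also lay lower. The largest falls also held Cxcl13, a B cell chemokine (log2 -3.20), Acod1, which makes itaconate in activated macrophages (log2 -2.86), and the leukocyte sialoprotein Spn (log2 -1.70).

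Fatty acid oxidation genes rose with Δ[O] in 4 of 17 (7 adjusted over the list alone; camera adjusted p = 7.95e-07, adjusted p = 0.177 with an estimated correlation), with the peroxisomal enzyme Ehhadh at log2 0.72. Acaa1b (649.9 ± 88.8 against 323 ± 52.1 CPM, log2 1.01) and Cyp4a10 (log2 1.92), which belong to the same programme, lost their calls with the replicate block (adjusted p = 0.0579 and 0.0603, over all alternatives 0.00494 to 0.16 and 0.00688 to 0.144). No cell cycle gene passed, 0 of 26 by edgeR (median log2 fold change -0.32; camera adjusted p = 0.00573, adjusted p = 0.604 with an estimated correlation), endothelium genes fell in 1 of 16 (camera adjusted p = 0.223), and Hmgb1 itself measured 74.5 ± 14.8 against 58.7 ± 13.4 CPM (adjusted p = 0.428).

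In all 326 genes differed, 16 higher and 310 lower with Δ[O]. The count was 151 without wild-type HMGB1 CCl4 library 3, 109 without library 4, 66 without library 5, and 73, 61 and 166 without Δ[O] libraries 1, 3 and 5, while 492 passed without Δ[O] library 2. DESeq2 called 573 and a fit of only these groups 108. Of 42 named genes past the test 9 kept their call under each alternative, Marco, Hmox1, Cxcl16 and Spn among them. Leaving out any 1 library except Δ[O] library 2 ended at least 1 of the other calls. The adjusted p then rose to at most 0.0748 for Col6a3, 0.0659 for Cd5l, 0.0508 for Cd163, 0.0924 for Timd4, 0.146 for Tgfb1, 0.0838 for Postn, 0.134 for Fbn1, 0.0892 for Icam1, 0.116 for Cxcl13, 0.119 for Acod1 and 0.123 for Ehhadh. With the block the TGF-beta (adjusted p = 0.0393), mesothelium (0.00977) and female-biased (0.0329) lists gained camera calls. Of 18 camera calls 0 held with an estimated correlation, and fry called 9 lists.

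Under MO, no gene passed for Δ[O] against wild-type HMGB1 in edgeR, with 1549 at an unadjusted p under 0.05 and 22 by DESeq2. Neutrophil genes lay lower with Δ[O] (5 of 11 adjusted over the list alone; median log2 fold change -0.89; camera adjusted p = 1.05e-06, adjusted p = 0.308 with an estimated correlation), with S100a9 at 14.3 ± 7.31 against 31.2 ± 6.08 CPM (n = 3 each, adjusted p = 0.339). Clock genes lay higher (3 of 16 adjusted over the list alone; camera adjusted p = 0.00467, adjusted p = 0.308 with an estimated correlation), and the protease list gained a camera call with the block (adjusted p = 0.0487). None of 10 camera calls held with an estimated correlation. Wild-type HMGB1 library 3 and Δ[O] library 3 held Xist at 845 and 664 CPM, and 823 genes passed without the former, 11 without the latter, 1 without wild-type HMGB1 library 1, 804 without both Xist-holding libraries and 4 with the replicate block.

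Hmgb1ΔHepΔMye livers with wild-type HMGB1 also differed from wild-type livers. Under CCl4 they held more proliferation and matrix transcript and less of the unfolded protein response. Col1a1 measured 506 ± 126 against 144 ± 49.8 CPM (SD, n = 4 each; log2 1.82, SE 0.45, adjusted p = 0.00566) and Plk1 differed by log2 4.22, whereas Creld2, an endoplasmic reticulum stress gene, measured 24.3 ± 7.08 against 188 ± 78 CPM (log2 -2.95). Unfolded protein genes were lower in 14 of 15 (camera adjusted p = 1.14e-17, adjusted p = 0.00258 with an estimated correlation), the 1 call of 14 that held with an estimated correlation. Cell cycle genes were higher in 16 of 26 (camera adjusted p = 1.99e-20, adjusted p = 0.19 with an estimated correlation), and Kupffer cell genes in 10 of 13 (camera adjusted p = 1.19e-10, adjusted p = 0.19 with an estimated correlation). Collagen genes were higher in 14 of 20 (camera adjusted p = 6.34e-07, adjusted p = 0.308 with an estimated correlation) and interferon-stimulated genes in 11 of 20 (camera adjusted p = 0.000109, adjusted p = 0.308 with an estimated correlation). Altogether 4069 genes differed under CCl4 (2230 higher, 1839 lower), and Hmgb1 passed only with the replicate block (log2 -0.48, adjusted p = 0.0179; 0.0179 to 0.53 over all alternatives). The block also gave the fatty acid oxidation list a camera call (adjusted p = 0.0131).

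Under MO 3423 genes differed between these genotypes, 1801 higher and 1622 lower in the Hmgb1ΔHepΔMye livers, of which library 3 held Xist at 845 CPM. Of 126 genes of the naming rule past the test, 76 kept their call whichever library was left out and 72 under every alternative, among them Ifit1, Isg15 and Cxcl1. Interferon-stimulated genes were higher in 16 of 20 (camera adjusted p = 3.47e-17, adjusted p = 0.0757 with an estimated correlation), with Ifit1 at log2 2.19 and Isg15 at 2.16, and so were 7 of 11 neutrophil genes (camera adjusted p = 7.47e-08, adjusted p = 0.146 with an estimated correlation). Cxcl1 measured 66 ± 23 against 2.75 ± 0.362 CPM (SD, n = 3 each; log2 4.59). Cholesterol synthesis genes were higher in 13 of 20 (camera adjusted p = 1.53e-09, adjusted p = 0.345 with an estimated correlation), and none of 18 camera calls held with an estimated correlation. The labels do not say whether these genotypes were littermates or wild-type livers got a construct or AAV8, so genotype and supply are not separated.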

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

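The rule for libraries far from the rest of their group, fixed before the data were examined, covered the groups of 4 CCl4 livers only, and no test here was chosen after a result was seen. A library stood apart where its gap to the nearest other library, over the range of the group, exceeded Dixon's critical value for 4 samples. Chance passes that limit in about 1 in 20 groups, and 13 of 174 values passed it. Scores are means over a list of log2 levels centred per gene.

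Wild-type CCl4 liver 4 stood apart in 4 values. Its Cyp2e1 was 1193 CPM against 170 to 262 in the other livers of the group. Its Cyp2b9, a female-biased cytochrome gene, was 18.2 CPM against 0.57 to 2.52. Its fatty acid oxidation score was 0.519 against -0.233 to -0.135, and its infiltrating macrophage score was 0.478 against 0.82 to 0.879. Wild-type CCl4 liver 2 had an immediate early score of 1.29 against 0.573 to 0.668, and a xenobiotic receptor target score of -0.718 against -0.193 to -0.0974.

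With wild-type HMGB1 under CCl4, liver 4 had an interferon-stimulated score of -0.167 against -0.0535 to -0.0334 and a mesothelium score of -1.91 against 0.512 to 0.97. Liver 3 of that group held Xist at 0.461 CPM against 0 to 0.0587. With Δ[O] HMGB1 under CCl4, liver 1 held Xist at 0.728 CPM against 0.106 to 0.198 and had a TGF-beta response score of -0.0884 against 0.314 to 0.325. Liver 3 held Fos, an immediate early gene, at 6.53 CPM against 1.85 to 2.23. Liver 5 had a periportal score of 0.329 against -0.299 to -0.219.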

How the results depend on the processing

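Fits without the Xist-holding libraries, with the female share as a covariate, without the fibrosis libraries numbered 2, and with a block in only the groups compared were chosen after seeing the data. Of 287 values of the 21 counts of changed genes under alternatives, 221 lay within 1.5 times the count reported and 66 did not. Of 10 covariances 5 moved. For lists with a camera call 772 of 1180 tests kept it and 408 lost it, and 72 of 1328 tests of the other lists gained one. For named genes with a call 14247 of 15971 tests kept it and 1724 lost it, and 51 of 4929 tests of the others gained one. None reversed. Among genes of the naming rule, every alternative kept the call of 94 of 103 for [O] and 88 of 95 for [SO3] against BSA, 119 of 140 for CCl4 in wild-type liver and 93 of 120 for the genotypes under CCl4.

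[H] against BSA in HSC-T6 cells gave 168 genes with no filter, 39 with the replicate block, 454 in a fit of only those groups and 139 with DESeq2. DESeq2 gave 2, 6 and 274 genes for [H], [O] and [O] against [H] in fibrotic liver, and 80, 3 and 35 for [SO3], the antibody and their difference in resolving liver. It gave 2329 for resolution against fibrosis, 573 and 22 for Δ[O] against wild-type HMGB1 under CCl4 and MO, and 81 for the difference of their CCl4 responses. A fit of only the groups compared gave 49 for [SO3], 9 for [SO3] against the antibody, 91 for resolution against fibrosis and 108 for Δ[O] against wild-type HMGB1 under CCl4. No filter gave 776 for resolution against fibrosis, and covariances of 0.24, 0.241 and 0.366 in the cells (the [H] and [O], [H] and [SO3], and [O] and [SO3] pairs; simulated 0.152, 0.155 and 0.154), 0.378 in fibrotic and 0.325 in resolving liver (simulated 0.268 and 0.233). The cause was not tested.

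The replicate block gave 1 gene for [O] against [H] in fibrotic liver and 4 for Δ[O] against wild-type HMGB1 under MO, both paired. In the 15 comparisons not fully paired, correlations ran from -0.252 to 0.454, and in 0 did every sample correlate best with its own number. There the block gave 2 for [SO3] in resolving liver and 39 for [H] in the cells. The difference of CCl4 responses, paired between constructs (up to 0.454) but not injections, gave 3. The other 12 stayed within 1.5 times. In paired comparisons, the block changed no call of a count, list or gene in the report beyond those given. The block with only the groups compared gave 230 for [O] against [H] in fibrotic liver, 231 for [SO3], 1 for the antibody, 36 for their difference and 5 for resolution against fibrosis.

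Without the Xist-holding libraries 79 genes passed for [SO3], 51 for [SO3] against the antibody, 704 for resolution against fibrosis, 804 for Δ[O] against wild-type HMGB1 under MO and 768 for the difference of CCl4 responses. The first 2 leave 1 [SO3] library and the third 1 fibrosis BSA library, each of which is assumed to vary like the other groups. The female share as a covariate gave 63 for resolution against fibrosis, 2 under MO and 34 for the difference of CCl4 responses. Without the fibrosis libraries numbered 2, 1 gene passed for [O] against [H].

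Leaving out each library gave 13 to 195 genes for [H] in the cells, 0 to 1 for [O] and 0 to 16 for [O] against [H] in fibrotic liver, and 0 to 2 for both [SO3] comparisons in resolving liver. It gave 0 to 2377 for resolution against fibrosis, 2127 to 4039 for CCl4 with Δ[O], 61 to 492 and 0 to 823 for Δ[O] against wild-type HMGB1 under CCl4 and MO, and 0 to 1119 for the difference of CCl4 responses. Depth limits rare transcripts most in resolving liver, where the shallowest library held 8.36 M gene counts against 22.6 M or more in the MO and CCl4 livers.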

Other observations

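The splits of the samples and the test without Δ[O] library 5 were fixed beforehand, and the other tests below were chosen after the results were seen. Circadian clock genes differed between the genotypes in livers given MO. With wild-type HMGB1 supplied, Hmgb1ΔHepΔMye livers held Npas2, an activator of the clock, at log2 5.73 relative to wild-type livers (5.94 ± 3.04 against 0.106 ± 0.0447 CPM, SD, n = 3 each). Per1 and Ciart, clock repressors, stood at log2 -2.86 and -3.76, and Nr1d1 at log2 2.57. Of the list 2 were higher and 9 lower of 16 (camera adjusted p = 0.000392, adjusted p = 0.146 with an estimated correlation). Under CCl4 2 were higher and 4 lower (camera adjusted p = 0.257), and the difference between these was not tested. Collection times are not given in the sources used here.

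Matrix and macrophage transcripts were lower with Δ[O] than with wild-type HMGB1 under CCl4, a name given to this pattern after cell cycle genes were found to pass in 0 of 26. The values argue against any 1 library deciding it. Whichever of the 8 was left out, at least 81.3% of the difference in the matrix, Kupffer and infiltrating macrophage scores was left, beyond 2 SE. The count of lower genes depended on single libraries, at 310 with all and 70, 456, 57 and 151 without Δ[O] libraries 1, 2, 3 and 5. It was 145, 107 and 65 without wild-type HMGB1 libraries 3, 4 and 5. Less bioactivation of CCl4 stays open. Cyp2e1 was at log2 0.92 (SE 0.51, adjusted p = 0.418), but injury lowers it, so this decides nothing. Under MO Cyp2e1 was no lower with Δ[O] (6444 ± 1080 against 5392 ± 513 CPM, n = 3). A smaller share of all non-hepatocyte cells stays open, after several forms of that test were tried. The Kupffer and endothelium medians lay up to 0.637 from the matrix median, and the range over all 10 cell type lists gave an exact permutation p of 0.4. The lists did not all fall, as a smaller share would need, with cholangiocytes at 0.102 and neutrophils at -0.0453 beside Kupffer cells at -0.813. The 70 permutations ignore the pairing by number, and the 8 splits that keep it are too few for a p under 0.05, so neither permutation p decides the question. A change in macrophages is likewise a hypothesis only.

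Transcripts of both sexes occurred in livers labelled male. By CPM without TMM factors, 29 of 39 liver libraries held Y-linked transcripts with Xist under 10 CPM, 5 held Xist with Y-linked genes under 5 CPM, and 5 held both. Mixing of male and female RNA could give both, and then the Y-linked level as a percent of males and the Xist level as a percent of females should sum to near 100. The sum lay outside 70 to 130 in 2 of these 5 (54.9 and 48.8, against 96.5, 108 and 122), and too few female libraries give the spread of Xist, so mixing stays open. Whether female RNA accounts for the female-biased genes of resolving livers with [SO3] HMGB1 is open too, since their mean log2 fold change was 5.49 without the Xist-holding libraries and 6.68 with them, but 1 [SO3] library remained.

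The [O] and [SO3] forms gave programmes in HSC-T6 cells that differed in part, while many of their changed genes were common to both. Greater depth than in the BSA libraries is argued against by the 4139 genes that differed between [O] and [H], whose depths lie closer. A shift of the scaling by a few abundant genes would move every list alike. It is argued against by the antioxidant score minus the cytokine score, which differed between [SO3] and [O] by 3.65 (SE 0.0563). A contaminant common to both preparations, such as endotoxin, could raise NF-kB genes in both and stays open, since their median log2 fold change was 0.96 with [SO3] and 2.63 with [O]. A biological effect of each form is likewise a hypothesis.

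Other splits of the same libraries tested chance. For 4 against 3 libraries, 1 of 35 splits, the real one, gave as many genes in each of 3 comparisons. These were CCl4 in wild-type liver (6542, highest other 5328, which put CCl4 liver 4 with the MO livers), with wild-type HMGB1 (6685, 3836) and with Δ[O] (3425, 3267). A share of 1 in 35 is the smallest these splits can give and is not adjusted over the comparisons. It makes chance unlikely but does not exclude it. In 2 comparisons of 4 against 4 libraries the numbers pair the samples, and the 8 splits that part every pair are too few for a share under 0.05. These were Δ[O] against wild-type HMGB1 under CCl4 (326, highest other of the 8 splits 0 and of all 35 splits 1) and the genotypes under CCl4 (4069, 2 and 11). For the difference of CCl4 responses the real count was 0, so that all 100 drawn splits gave as many by necessity and test nothing, and the highest other was 315.

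For 3 against 3 libraries, 10 splits are too few for a share under 0.05. In HSC-T6 cells the real counts were 81 to 6431, and the highest of the other splits was 0 in each comparison. The real counts were 1214 for resolution against fibrosis (highest other 0) and 3423 for the genotypes under MO (1231). In [H], [O] and [O] against [H] in fibrotic liver the real count was 0 and the highest others 286, 1 and 10, but 0 among the 4 splits that part every pair. In resolving liver both counts were 0. For Δ[O] against wild-type HMGB1 under MO they were 0 and 61 (0 among the 4 that part every pair). Splits with 286 and 61 genes for a real 0 point to structure beyond the groups. That with 315 kept the real CCl4 groups and does not. That with 286 set BSA 1, BSA 3 and [H] 1 apart, and that with 61 left both Xist-holding libraries on 1 side.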
